A study of Oryza sativa with 6 samples.

How the data were processed

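Small RNA of 6 samples was sequenced, with 1 library per group. Roots and shoots of 7-day-old seedlings and de-husked grains of 1-5 and 6-10 DAF were sequenced with 454, and the grain stages also with Illumina. For 454, per the labels, low molecular weight RNA was cut from a gel between markers of 18 and 25 nt, ligated to adaptors, reverse transcribed and amplified. The Illumina libraries were made from total RNA outside the laboratory, and the labels do not say whether it was the RNA used for 454, so the platforms stood as replicates of a stage only in the tests over the 4 grain libraries, with platform as a term.

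The deposited tables give each distinct tag and its abundance in RPM, reads scaled to the total reads of the library, per the file headers, as made by the authors. Tags shorter than 18 nt were left out of them, and tags were kept whether or not they match the rice genome. The program that removed the adapters is not stated. Each table lists the tags of all libraries of its platform, with 0 where a library has none. Reads were recovered as the value divided by the value of 1 read in that library, and 100% of values came out whole within the rounding of the printed decimals, a tolerance between 6.03e-05 and 0.0171 reads by library. The listed tags held 91.1% of the total reads in 454 grains of 1-5 DAF, 93.4% at 6-10 DAF, 87.2% in roots, 94.8% in shoots, and 95.7% and 89.2% in Illumina grains. The deposited Illumina reads, 33 nt long with the adapter still on, hold as many reads as the header totals and were used to count insert lengths and base quality. An adapter was found from an overlap of at least 6 nt with up to 15% mismatches.

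miRNA sequences and names were written from memory of miRBase before the data were examined. They comprise 119 sequences of 56 mature families (1 of them the tasiRNA tasiR-ARF, counted here with the miRNA families) and 12 opposite arms in 11 lists, 10 of them of mature families. The names were not checked against a reference here, so a name stands for the exact sequence searched. A family is the sum of the tags identical to its sequences. As an alternative, tags of 18 to 25 nt were counted that hold the 16-nt core of a listed sequence (its bases 3 to 18) starting within the first 5 bases of the tag. The list of grain miRNAs named from this series was chosen by the study on these samples. Opposite-arm shares were taken over the reads of both arms.

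Libraries were compared as RPM of the header total. Families and tags with at least 20 reads over both libraries were tested with a two-sided Fisher's exact test on the reads of the 2 libraries, adjusted after Benjamini and Hochberg over the families or tags compared. A call needed an adjusted p of 0.05 or less and a ratio of at least 2 in either direction. Ratios carry an exact conditional 95% interval, and shares an exact Clopper-Pearson 95% interval. Where a library had 0 reads, a floor of 3 reads gives the bound. With 1 library per group these tests describe the libraries. Grains and seedlings were compared in all 4 pairs of 454 libraries, and a family counted only when called in the same direction in every pair. They were also tested with edgeR over the 4 libraries, with the 2 stages and the 2 organs as the samples of each side, so that the spread includes differences between stages and organs. Stage ratios were compared between platforms with Zelen's exact test. Members of a family with at least 20 reads over both Illumina stages were compared in pairs with Fisher's exact test on the reads of 2 members at 2 stages, adjusted over 13 pairs, a test added after the data were seen. Correlations between platforms used log2 of RPM plus 1, across families with at least 20 reads over both platforms, a limit set on the platforms together after the first results were seen. The medians of the lists were ranked among 10000 random lists of tags of like abundance, or of like abundance and length.

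Families were named by a rule fixed before the data were examined. It takes up to 12 called families with the largest ratio in each direction, the 3 most abundant families, and the most abundant uncalled family of each list. For tags outside the lists it takes the 3 most abundant per library and, among called tags with at least 100 reads in a library, the 3 with the largest ratio in each direction. Between shoots and roots it gives 1 such tag. Families and tags named outside this rule are identified where they appear.

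The alternatives fixed before the data were examined were a denominator of reads matching a listed mature family or of 20 to 22 nt reads, TMM scaling, core matching, count minimums of 5 and 100 reads, a ratio of 1.5, length shares without tags seen once or without listed sequences, and tests of stage over the 4 grain libraries with platform as a term in edgeR and DESeq2. Chosen after seeing the data were a denominator of listed reads, a denominator of reads of the same length, the removal of tags made of adapter, the comparison of all tags between the 454 grain stages, edgeR over the 2 grain and 2 seedling libraries, and DESeq2 with size factors from the library totals. The last of these was added because DESeq2 with its own size factors recovered few simulated changes.

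Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. The tests were tested on simulated data drawn from the measured levels, with 4-fold changes put in. Counts were drawn as Poisson, with no variation between libraries beyond counting. The recoveries and false calls therefore hold for counting error only. Of 10 changed families in the Illumina comparison 10 were recovered with 0 false calls, and of 198 changed tags above the minimum 117 were recovered (59.1%) with 1 false call over 25489 tags. In the 454 comparisons 2 of 2 changed families between grain stages, 1 of 1 between shoots and roots, and 10 of 10 tags between shoots and roots were recovered. Over the 4 grain libraries, edgeR recovered 7 of 10 changed families with 2 false calls, DESeq2 1 of 10 with 0 false calls, and DESeq2 with library totals 4 of 10 with 0 false calls. Between grains and seedlings edgeR recovered 1 of 1 changed family with 0 false calls under either scaling. The simulation over the 4 grain libraries was corrected once, after its first result, so that the simulated levels follow the library totals.

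A rice genome was not used here. Matches to the genome, the share of reads in other RNA classes and the precursors of miRNA-like small RNAs were therefore not examined, and tags outside the lists are described by sequence alone, without a position in the genome.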

Results

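Small RNAs of rice cultivar Nipponbare were sequenced from developing grains at 1-5 and at 6-10 days after fertilization (DAF) and from roots and shoots of 7-day-old seedlings. The roots, the shoots and both grain stages were sequenced with 454 pyrosequencing, and the grain stages also with Illumina, which gave 6 libraries with 1 library per group and no replicates. The 454 libraries held 46879 reads (grains 1-5 DAF), 55391 reads (grains 6-10 DAF), 21697 reads (roots) and 11866 reads (shoots), and the Illumina libraries held 3428861 reads (1-5 DAF) and 3412945 reads (6-10 DAF). A single read stood for 21.3, 18.1, 46.1 and 84.3 RPM in these 454 libraries and for 0.292 and 0.293 RPM in the Illumina libraries. Most distinct tags were seen once, from 82.2% of tags in Illumina grains of 1-5 DAF to 96.3% in shoots. The stages shared 308332 tags in Illumina, 21.1% of the tags of 6-10 DAF, and 2614 tags in 454, 5.96% of the tags of 6-10 DAF. The Fisher's exact tests below compare the reads of 2 libraries and not the conditions, and all intervals and floors cover counting error only.

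Listed mature miRNAs, the families known from rice and other plants together with families first named from developing grains, made up a small part of each library. They took 4.18% of reads in Illumina grains of 1-5 DAF (exact Clopper-Pearson 95% interval 4.16% to 4.20%) and 7.58% at 6-10 DAF (7.55% to 7.60%). In 454 they took 0.512% of reads at 1-5 DAF (0.449% to 0.581%), 0.442% at 6-10 DAF (0.389% to 0.501%), 1.88% in roots (1.70% to 2.07%) and 3.75% in shoots (3.42% to 4.11%). In Illumina grains miR168, which targets the mRNA of the slicer ARGONAUTE1, was the most abundant family, with 97510 and 164855 reads at the 2 stages. It was followed by miR156, which targets SPL transcription factors, and by miR166, which targets class III HD-ZIP transcription factors. Of the 56 mature families looked for, 40 had at least 20 exact reads over the 6 libraries. Another 8 had no read identical to a listed sequence, among them miR395 of sulphate uptake and miR2275, a trigger of phased small RNAs in panicles. Counted with reads of differing ends, only miR1430 of these 8 had none. miR1867 had 55 and 147 such reads at the 2 Illumina stages and miR1423 had 13 and 58, both named after their values were seen.

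The length classes of the small RNAs differed between the grain stages in Illumina. The 24-nt class, which in plants guides DNA methylation and silences transposons, held 66.0% of listed reads at 1-5 DAF and 49.1% at 6-10 DAF, a ratio of the shares of 0.744 (95% interval 0.742 to 0.745). The 21-nt class, which holds most miRNAs, went from 9.39% to 19.5%, a ratio of 2.08 (2.07 to 2.09). In 454 the 24-nt share was 49.6% at 1-5 DAF and 50.6% at 6-10 DAF, a ratio of 1.02 (1.00 to 1.04), and the 21-nt share went from 7.56% to 10.8%, a ratio of 1.43 (1.36 to 1.49). Roots held 42.0% of 24-nt reads (exact interval 41.3% to 42.7%) and shoots 51.7% (50.7% to 52.6%), with 9.92% and 11.0% of 21-nt reads. Without tags seen once, the 24-nt share dropped to 12.7% in roots and 15.2% in shoots. Inserts under 18 nt, which the tag tables leave out, made up 3.90% of the Illumina reads at 1-5 DAF and 11.3% at 6-10 DAF.

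**Figure D1:**
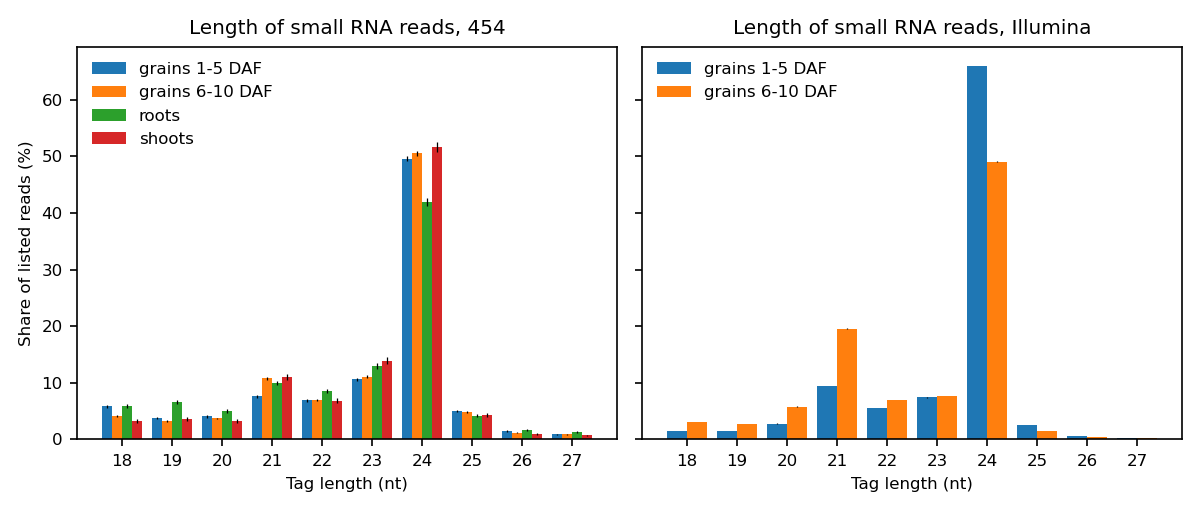
Percentage of listed reads at each tag length (x axis, nt) in each library, in the 454 (left) and Illumina (right) libraries, with exact 95% intervals as error bars. The 24-nt class held 66.0% of reads in Illumina grains of 1-5 DAF and 49.1% at 6-10 DAF, against 49.6% and 50.6% in 454.

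The series asks which known miRNAs and miRNA-like small RNAs developing grains hold, and the Illumina libraries give the deepest comparison of the grain stages. At 6-10 DAF, 2 miRNAs that target mRNAs of copper proteins, miR528 and miR408, were higher than at 1-5 DAF, in a library that also held more inserts under 18 nt (11.3% against 3.90%). miR528, which targets copper oxidases such as ascorbate oxidase, rose 7.51-fold (443 to 3312 reads, 95% interval 6.80 to 8.31). miR408, which targets plantacyanin and laccases, rose 17.1-fold (4 to 68 reads, 6.37 to 64.5), or 12.8-fold with reads of differing ends. miR529, which shares SPL targets with miR156, fell 3.43-fold (479 to 139 reads, 2.83 to 4.17), while miR156 itself rose 2.22-fold (29514 to 65356 reads, 2.19 to 2.26), a rise that was not called under 4 of the 6 scalings described below (lowest ratio 1.10). Of 40 families with at least 20 reads over both libraries, 22 rose, 2 fell and 16 were not called (Fisher's exact test on reads, two-sided, Benjamini-Hochberg adjusted p of 0.05 or less and a ratio of at least 2). Beside miR529, the other family that fell was miR1432 (17 to 6 reads, 2.82-fold lower, 1.06 to 8.74, exact test adjusted p = 0.0448). Counted with reads of differing ends, miR1432 went from 453 to 226 reads, a ratio of 0.501 that just missed the threshold.

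The median family had a log2 ratio of 1.11, and the split between rises and falls depended on the denominator. Per read that matched a listed mature family, 8 families were called up and 6 down, with a shift of -0.86 in the median log2 ratio. The split was 9 up and 6 down per 20 to 22 nt read (shift -0.77), 8 and 8 with TMM scaling (-1.01), 14 and 7 per read of the same length (-0.95), and 23 and 2 per listed read (0.10). Of the 22 families that rose, 8 were called up under all 6 scalings, namely miR408, miR528, miR820, miR1428, miR1859, miR1873, miR1874 and miR1877. The scalings were run on exact matches, and reads of differing ends were compared per library total only. For miR820 the exact matches were 13 and 81 reads, against 1300 and 4031 with reads of differing ends. Whether most of its reads would be called under all 6 scalings was therefore not tested. Over these scalings miR408 was between 8.48-fold and 18.3-fold higher and miR528 between 3.73-fold and 8.06-fold higher. miR529 and miR1432 were called down under all 6. Tests of stage over the 4 grain libraries, with platform as a term, called 0 families with edgeR (1 at an unadjusted p under 0.05) and 0 with DESeq2 (4 at an unadjusted p under 0.05).

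Among the lists fixed before the data were examined, all 3 compared copper families rose, while miR398, with 1 and 2 reads, was too rare to compare. Beside miR408 and miR528 this was miR397, which targets laccases (5 to 18 reads, 3.62-fold, 1.29 to 12.5), and all 3 were also called when adjusted over the list alone. miR397 was not called under 4 of the 6 scalings. The median log2 ratio of the copper sequences, 2.91, lay at percentile 99.6 of 10000 random lists of tags of like abundance and at percentile 97.3 of tags of like abundance and length. With 3 sequences this median is the log2 ratio of miR528 itself, so the percentiles add little to its call. They make no allowance for the number of lists ranked. Of 4 phase change and flowering families, 2 rose and 1 fell (3 adjusted over the list alone), with miR535, another SPL regulator, 3.02-fold higher (2.80 to 3.25), though not called under 4 of the 6 scalings (lowest ratio 1.50). miR172, which targets AP2-like transcription factors, had a ratio of 1.82 (1.24 to 2.71) and was not called, and its direction turned with TMM and same-length scaling, to 0.905 and 0.941. The percentiles of this list were 89.5 for abundance and 21.9 for abundance and length.

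miRNAs of auxin signalling and of developmental transcription factors were mostly not called per library total, but 2 of 5 auxin families (miR393, 0.224, and tasiR-ARF, 0.351) and 2 of 5 developmental families (miR159, 0.399, and miR171, 0.466) were called down with TMM scaling and per read of the same length. The first 3 of these were also called down per listed mature miRNA read and per 20 to 22 nt read. Counted with reads of differing ends, tasiR-ARF turned to a ratio of 1.74 (63 to 109 reads, not called). In that count miR393 was called down per library total (35 to 16 reads, 0.459), and miR159 and miR171 were not called (0.776 and 0.877). Of 5 auxin families, 1 of which is the tasiRNA tasiR-ARF and not a miRNA, 4 were not called per library total with exact matches. The other, miR390, which triggers tasiRNAs against auxin response factors, rose 2.46-fold (1.95 to 3.13), but was not called under 4 of the 6 scalings (lowest ratio 1.22, 1 family adjusted over the list alone, percentiles 77.3 and 6.84). The ratio of miR167, which targets auxin response factors, was 1.56 (1.48 to 1.64), and it lay below 1 under 4 of the scalings, at 0.859, 0.916, 0.773 and 0.804. Of 5 developmental families, miR164, which targets NAC transcription factors, rose 2.33-fold (2.16 to 2.51) and 4 were not called (1 adjusted over the list alone, percentiles 58.9 and 0). The rise of miR164 was not called under 4 of the 6 scalings either (lowest ratio 1.16). miR166, with 7803 and 9546 reads, had a ratio of 1.23 (1.19 to 1.27), and it lay between 0.610 and 0.723 under the same 4 scalings. Neither family of the small RNA machinery was called (0 adjusted over the list alone, percentiles 86.5 and 38.4). miR168 had a ratio of 1.70 (1.69 to 1.71), and it lay between 0.843 and 0.999 under these 4 scalings.

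Nutrient and grass miRNAs rose in part. The rises of miR827, miR169 and miR444 were each called under only 2 of the 6 scalings, with lowest ratios of 1.34, 1.08 and 1.04, and that of miR169 was not called with reads of differing ends either (1.77). miR827, which targets phosphate transporters with an SPX domain, rose 2.71-fold (2.27 to 3.25). It was the 1 phosphate and sulphate family compared, so its call over the list alone involved no adjustment. Of 2 other conserved families, miR169, which targets NF-Y transcription factors, rose 2.18-fold (1.32 to 3.69), and miR394 had a ratio of 0.920 (0.624 to 1.35) and was not called (1 adjusted over the list alone), but was called down with TMM scaling (0.456) and per read of the same length (0.471). Of 5 grass and rice families, 3 rose and 1 fell (4 adjusted over the list alone, percentiles 94.2 and 35.7). miR820, which targets a DNA methyltransferase gene, rose 6.26-fold (13 to 81 reads, 3.46 to 12.3), but most of its reads had differing ends, and with these it rose 3.12-fold (1300 to 4031 reads). miR1428 rose from 1 to 20 reads, a ratio of 20.1 (3.21 to 833), or 11.1 with reads of differing ends, and miR444, which targets MADS-box genes, rose 2.09-fold (1.90 to 2.32). miR1425 had a ratio of 1.06 (0.903 to 1.26) that lay between 0.528 and 0.626 under the same 4 scalings. No panicle phasiRNA trigger reached 20 reads. The values of miR535, miR390, miR164, miR827, miR169 and miR444, and those of miR393, tasiR-ARF, miR159 and miR171 above and of miR1850, miR1868, miR1879, miR1881 and, in 454, miR820, miR528 and miR535 below, were chosen after they were seen.

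Of 13 miRNA families first named from developing grains, 10 rose, 0 fell and 3 were not called (11 adjusted over the list alone). Under all 6 scalings only 4 of the 10 were called. miR1881, not called per library total (0.833), was called down per listed mature miRNA read (0.460), per 20 to 22 nt read (0.490) and with TMM scaling (0.414). With reads of differing ends its ratio was 1.10, not called. This list was chosen by the study on these samples, so its direction is not independent evidence. miR1877 rose 10.8-fold (21 to 225 reads, 6.87 to 17.7), miR1859 7.68-fold (25 to 191 reads, 5.04 to 12.2), miR1873 4.88-fold (7 to 34 reads, 2.13 to 13.0) and miR1874 4.32-fold (66 to 284 reads, 3.30 to 5.74). miR1883 and miR1884 each rose 3.82-fold (5 to 19 reads, 1.38 to 13.1) and miR1862 3.50-fold (27 to 94 reads, 2.26 to 5.58), without being called under all 6 scalings. Nor were miR1850, miR1868 and miR1879, whose lowest ratios were 1.06, 1.02 and 1.72. The most abundant uncalled family, miR1870, had a ratio of 1.34 (1.14 to 1.59) that lay between 0.668 and 0.791 under 3 scalings. The median of the list lay at percentile 100 of both kinds of random lists.

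**Figure D2:**
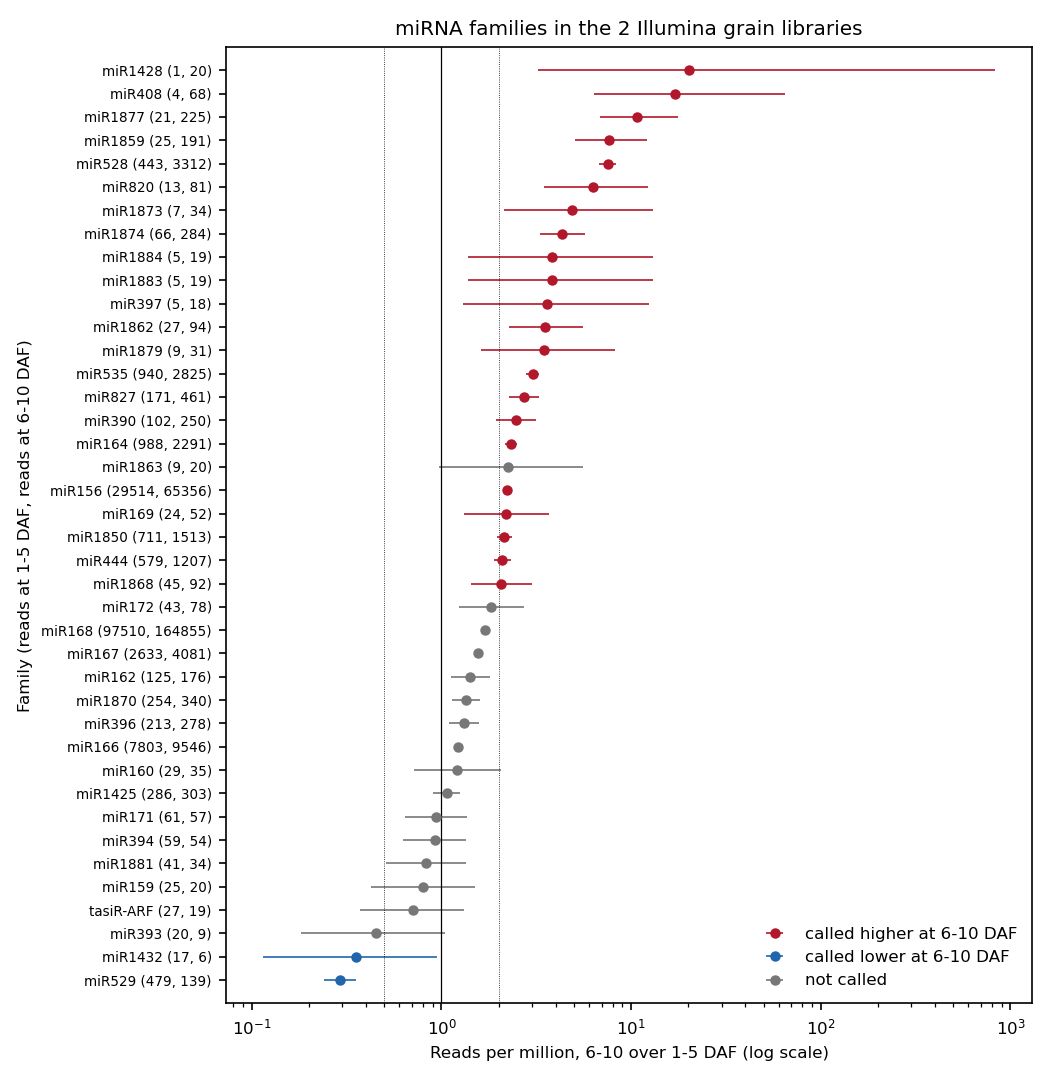
Ratio of RPM, 6-10 over 1-5 DAF in Illumina (log axis), for each of the 40 families compared, ordered by ratio, with its exact 95% interval (bars), its reads at both stages in parentheses and its call by colour. Dotted lines mark the ratio threshold of 2 in either direction, and miR408 (17.1) and miR528 (7.51) lie far above 1 and miR529 (0.292) far below it.

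In 454 the same stages could be compared for 4 families only. miR171, which targets GRAS transcription factors, fell 3.98-fold from 118 to 35 reads (2.71 to 5.99), and miR167 fell 12.4-fold from 21 to 2 reads (3.03 to 109). The ratio of miR168 was 1.95 (66 to 152 reads, 1.45 to 2.64), just under the threshold, and the ratio of miR169 was 1.13 (0.501 to 2.61), which lay below 1 with 20 to 22 nt, TMM and same-length scaling. By Fisher's exact test 0 families rose and 2 fell, and both were also called under all 6 scalings. Each was the only family of its list compared, so its call over the list alone involved no adjustment. miR168 was called up per listed mature miRNA read (2.26, for 1 up and 2 down) and with reads of differing ends (2.04, for 2 up and 2 down). With exact matches, none of the copper, phase change, grass or grain families reached 20 reads in these libraries. With reads of differing ends miR820 did (4 and 27 reads). At 6-10 DAF miR528 had 1 read in 454, where its Illumina share gives 53.8 reads. miR535 had 0 reads, where its share gives 45.8. The Illumina levels of miR528 and miR535 at 6-10 DAF were thus not seen in 454.

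Shoots and roots of seedlings were compared for 2 families. miR168 was 2.03-fold higher in shoots (302 reads in roots and 336 in shoots, 1.74 to 2.38), and miR171 was 2.11-fold higher (52 and 60 reads, 1.43 to 3.12). Both were called by Fisher's exact test (adjusted p of 4.47e-19 and 9.48e-05 by the exact test). As each was the only family of its list compared, a call over the list alone involved no adjustment. Neither was called under 4 of the 6 scalings. The ratios of miR168 and miR171 were 1.02 and 1.06 per listed mature miRNA read and 0.988 and 1.02 with TMM scaling. They were 1.87 and 1.94 per listed read and 1.69 and 1.75 per read of the same length, where only the ratio missed the threshold. Counted with reads of differing ends, miR171 had a ratio of 1.80 and was not called, and miR820 was compared too and was called lower in shoots (69 and 17 reads, 2.22-fold).

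miR168 was lower in both grain libraries than in both seedling libraries in 454. At 1-5 DAF it was 9.89-fold lower than in roots (7.55 to 13.1) and 20.1-fold lower than in shoots (15.4 to 26.6). At 6-10 DAF it was 5.07-fold lower than in roots (4.16 to 6.21) and 10.3-fold lower than in shoots (8.49 to 12.6). miR171 was 3.79-fold lower at 6-10 DAF than in roots (2.42 to 6.00), 8.00-fold lower than in shoots (5.19 to 12.5) and 2.01-fold lower at 1-5 DAF than in shoots (1.45 to 2.76). Against roots, miR171 at 1-5 DAF had a ratio of 1.05 (0.752 to 1.48) and was not called. Of 2 families with at least 20 reads in all 4 pairs of libraries, 1 was lower in both grain libraries and 0 were higher by Fisher's exact test. Per listed mature miRNA read and with TMM scaling, miR168 was not called lower in all 4 pairs, and the ratios of miR171 called lower here lay above 1, from 1.06 to 3.65. Of the listed mature miRNA reads, miR168 took 66 of 240 at 1-5 DAF and 152 of 245 at 6-10 DAF. It took 302 of 407 in roots and 336 of 445 in shoots, so at 6-10 DAF little of the difference was left. A test of the 2 grain against the 2 seedling libraries, added after seeing the data, called 0 of 4 families with edgeR on library totals (1 at an unadjusted p under 0.05, miR168, 10.1-fold lower, edgeR adjusted p = 0.0568) and 0 with edgeR and TMM scaling (0 at an unadjusted p under 0.05).

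The platforms ranked the miRNA families differently in grains. At 1-5 DAF, miR156 was 135-fold lower in 454 (3 reads, with 404 given by its Illumina share), miR166 had 0 reads in 454 (at least 35.6-fold lower) and miR171 was 141-fold higher in 454 (103 to 196). Across 30 families with at least 20 reads over both platforms, Pearson's r of log2 RPM was 0.452 and Spearman's rho 0.429 at 1-5 DAF. At 6-10 DAF they were 0.405 and 0.219 across 36 families. Only 16 of the 30 families at 1-5 DAF and 17 of the 36 at 6-10 DAF had a read in 454. The others were tied at 0 reads there. Across families with at least 100 reads the order of the stages turned, with r of 0.235 and rho of 0.207 at 1-5 DAF (17 families) and 0.748 and 0.591 at 6-10 DAF (19 families). For the ratio between stages, 4 families could be compared, of which 3 had the same sign and 0 were called on both platforms (r of 0.477, rho of 0.60). This holds per library total: miR171 was called down on both platforms with TMM scaling (0.213 in 454, 0.466 in Illumina) and per read of the same length, where 2 of the 4 had the same sign. With reads of differing ends, miR820 was called up on both (5.71 and 3.12), and 5 of 6 families had the same sign. miR167 fell in 454 but had a ratio of 1.56 in Illumina, and Zelen's exact test found the stage ratios of miR167 (adjusted p = 1.41e-07) and miR171 (adjusted p = 1.20e-06) to differ between platforms. Families are not independent replicates, and the labels do not say whether both platforms sequenced the same RNA.

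**Figure D3:**
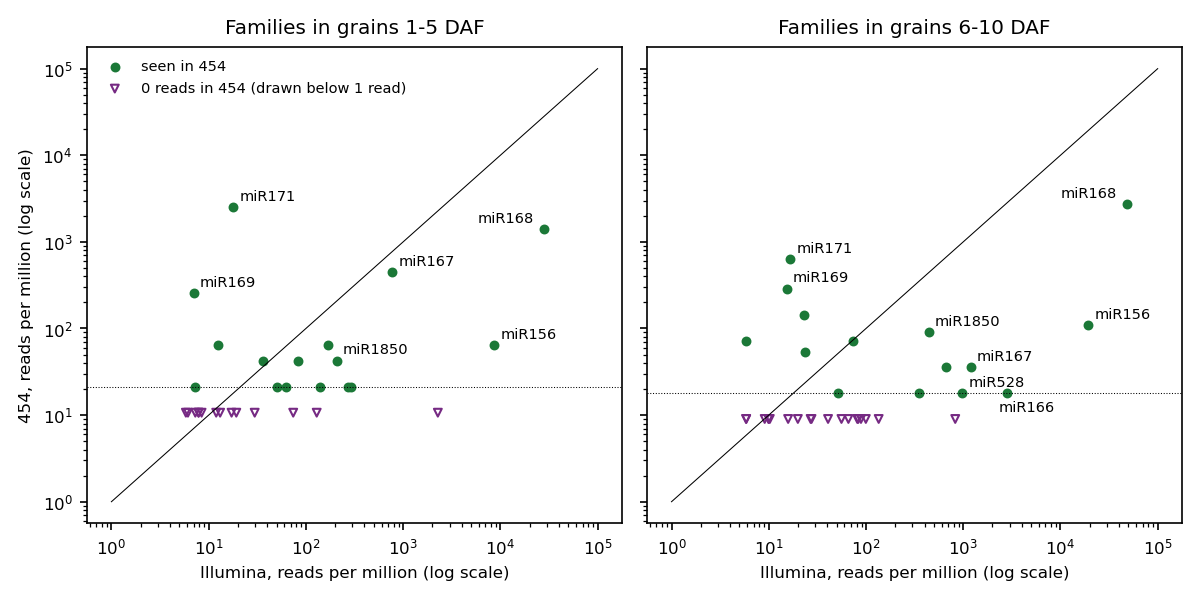
Level (RPM) of each family in Illumina (x axis) and 454 (y axis) at each grain stage, both on log axes, with the line of equal level and a dotted line at 1 read in 454. Open triangles mark families with 0 reads in 454, drawn below 1 read, and miR156, at 3 reads in 454 at 1-5 DAF, lies far below the line while miR171 lies far above it.

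Over all tags, more 21-nt tags rose than fell and more 24-nt tags fell than rose between the Illumina grain libraries. Among 1937 tags of 21 nt, 931 rose and 81 fell (median log2 ratio 1.09), and among 21313 tags of 24 nt, 1233 rose and 8055 fell (median -0.95). In total 28123 tags were compared, of which 3471 rose and 8649 fell by Fisher's exact test. Relative to reads of the same length, 3459 were called up and 3905 down, among them 519 up and 279 down at 21 nt and 2425 up and 3087 down at 24 nt, and relative to reads of 20 to 22 nt, 1258 up and 16405 down. The largest rises among called tags of at least 100 reads in a library were in ATGCAAGTGATGTAGCGCCC (1 to 116 reads, 117-fold, 20.5 to 4642), CACTTAAGGGTGATCGCGCGG (1 to 109 reads, 110-fold, 19.2 to 4365) and TGCAGAGGTCGCGGCGTTCAA (1 to 108 reads, 109-fold, 19.1 to 4325). The largest falls were in 24-nt tags, led by GTGATGTGTAGCACAATGCGGCTT (124 to 13 reads, 9.49-fold lower, 5.35 to 18.3), AGGGGCTGCCAAGGCAACCAGGGC (8.69-fold lower, 5.08 to 16.0) and CGGAGCAATGCGTTCTGATCGCCA (8.54-fold lower, 5.58 to 13.6). The rise named first, 117-fold, started from 1 read of a 20-nt tag. This tag equals a 21-nt tag, named under other observations, without its last base. That 21-nt tag went from 471 to 10460 reads, a rise of 22.3-fold, so the 117-fold rise is not that of a separate RNA. In 454, a comparison added after seeing the data, 117 tags were compared between the grain stages, and 15 rose and 52 fell by Fisher's exact test. Of its 27 tags of 21 nt, 9 rose and 7 fell (median log2 ratio 0.00), of its 11 tags of 24 nt, 2 rose and 4 fell (median -0.77), and of its 21 tags of 18 nt, 0 rose and 10 fell.

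The most abundant tags outside the lists differed by platform. In Illumina, TTGACAGAAGAGAGTGAGCAC, which holds a listed miR156 sequence, had 11416 reads at 1-5 DAF and 17261 at 6-10 DAF, and TGAAGCTGCCAGCATGATCTGA, which holds a miR167 sequence, had 2997 reads at 1-5 DAF. A tag made of adapter sequence had 5521 and 17698 reads, and tags of this kind took 0.366% and 1.01% of the reads. ATATAGGAGTCACTCAGGAAA had 12685 reads at 6-10 DAF and 270 at 1-5 DAF. In both 454 grain libraries the leading tags were the 18-nt GTCCTCGTGTTGCATCCC (275 and 141 reads), CTCCCACTGTGGTCGCCA (264 and 219 reads) and GTCCCACTGGGCGTGCCA (193 and 120 reads). Between shoots and roots 26 tags were compared, and 9 were higher and 13 lower in shoots. GACCGCATAGCGCAGTGGA was the most abundant tag of roots and was 13.8-fold lower in shoots (252 and 10 reads, 7.37 to 29.1). After it, roots held CAAGTTATGCAGTTGCTGCCT (60 reads) and CCGGAAGCCTGGTTACGGTGCC (47 reads), and shoots were led by GACCGCGTGGCCTAATGGA (46 reads), GACCGCGTGGCCTAATGG (38 reads) and TGTCGTGCCAATCCAACATAAGCCT (36 reads).

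The listed opposite-arm strands, from the side of the miRNA duplex that is usually degraded, were rare in Illumina grains. Over 12 families they made up 0.125% of the reads of both arms at 1-5 DAF (0.107% to 0.145%) and 0.435% at 6-10 DAF (0.410% to 0.462%). These pooled shares rest mostly on mature miR168 and miR156, with 97510 and 29514 of the 139604 reads at 1-5 DAF. The opposite arms listed for miR166, miR528 and miR827 had no read in any library, while their mature reads stay in the pooled shares. A single opposite-arm sequence was listed per family, so other variants of that arm were not counted. For miR408 the opposite arm was the more abundant strand, with 83.3% of the reads of both arms at 1-5 DAF (62.6% to 95.3%) and 90.0% at 6-10 DAF (87.5% to 92.1%). For miR393, an auxin receptor regulator, it was 33.3% at 1-5 DAF (10 opposite-arm and 20 mature reads, 17.3% to 52.8%) and 71.0% at 6-10 DAF (22 and 9 reads, 52.0% to 85.8%), and with core matching 61.0% there (25 and 16 reads, 44.5% to 75.8%). For miR167 its share was 3.55% (2.89% to 4.32%) and 8.62% (7.81% to 9.48%). With core matching the share of miR167 was lower, at 1.73% (1.42% to 2.09%) and 3.81% (3.46% to 4.17%). In 454 the share over the 12 families was 6.06% at 1-5 DAF (2.26% to 12.7%), 0.592% at 6-10 DAF (0.0150% to 3.25%), 0.906% in roots (0.187% to 2.63%) and 0.560% in shoots (0.0679% to 2.01%), from 6, 1, 3 and 2 reads.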

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

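All tests in this part were chosen after the result was seen, except the tests of differing ends of miR156 reads and of lengths within ladders of tags, and the test of the 5′ base replaced an earlier one that could not decide the explanation, with its bounds set after the values were seen.

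The stage effect of 2 families differed between the platforms in grains. For miR167 the log2 ratio of 6-10 over 1-5 DAF differed by -4.27 between 454 and Illumina (0.0806 in 454, from 21 and 2 reads, and 1.56 in Illumina). For miR171 it differed by -1.90 (0.251 in 454 and 0.939 in Illumina). This gap depended on the scaling. Per listed mature miRNA read the ratios of miR171 were 0.291 and 0.518, and with TMM scaling it was called down on both platforms. Over the 6 scalings miR167 lay between 0.0552 and 0.0933 in 454 and between 0.773 and 1.67 in Illumina. Zelen's exact test gave adjusted p values of 1.41e-07 and 1.20e-06 for these over 4 families compared, with miR168 (difference 0.20, exact adjusted p = 0.470) and miR169 (-0.95, exact adjusted p = 0.217) not past the threshold. Platform and library preparation changed together, and the cause of these differences was not tested.

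miR156 was far lower in 454 than in Illumina, with 3 reads at 1-5 DAF where its Illumina share gives 404. Sampling of the shallow library is argued against, since the observed number was 0.00743 of that and far under the 95% Poisson range of 365 to 443 reads. Reads lost to differing ends are argued against too, as the level of tags with a miR156 core in 454 was 0.00522 of the Illumina level (0.00108 to 0.0153). A platform preference for the 5′ base as the whole source is argued against, as miR156 begins with T and the share of reads outside the lists that begin with T was in 454 at the least 0.368 of that in Illumina (21-nt reads at 6-10 DAF, against 0.927 for 24-nt reads). Different RNA or ligation in the preparations stays open and was not tested.

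Inserts under 18 nt, which are in the deposited Illumina reads but not in the tag tables, made up 3.90% of reads at 1-5 DAF and 11.3% at 6-10 DAF. The same library had more short tags and fewer 24-nt tags. A fall of the 24-nt share with stage that any platform would see is argued against by 454. The ratio of the 24-nt shares was 1.02 there (1.00 to 1.04). A share depends on the other classes, though. In 454 the 18-nt share fell (ratio 0.695) and the 21-nt share rose (1.43). A fall of 24-nt reads relative to 21-nt reads is therefore not argued against. More short fragments or another length window in the 6-10 DAF library cannot be told apart from a change of the RNA: within 533 ladders of tags sharing their first 18 bases, tags of 23 nt or more lay below tags of 21 nt or less by a median log2 ratio of -0.98 (-1.06 to -0.90), between the bounds of -1 and -0.5 set beforehand, and the classes as a whole differed by -1.93. Of 264 tags of 21 nt with at least 100 reads, 54 lay over 4-fold above and 8 over 4-fold below the median of the class, a spread that 1 library per stage cannot part into variation between libraries and change with stage.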

How the results depend on the processing

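Denominators of listed reads and of reads of the same length, DESeq2 with size factors from the library totals, edgeR over the 2 grain and 2 seedling libraries, the removal of adapter tags, and the 454 stage comparison of all tags with its alternatives were chosen after seeing the data. Over the named families and tags, 550 values under an alternative were computed. Of these, 367 kept their direction and their side of the threshold, and 120 kept their direction but were no longer called. Another 10 became called and 53 changed direction. Other read minimums, a lower ratio threshold and the removal of adapter tags leave each ratio as it was, so direction could not change under them. Nearly all values under these settings are among the 367, which therefore overstates how stable the directions were. The causes of the changes below were not tested, except that fewer families or tags have 100 reads and that leaving out listed sequences or tags seen once removes reads of given lengths. The alternatives limited to genome matches, and 1 mismatch to the genome, were not run, since a genome was not used here. In 454, 4 families between grain stages and 2 between shoots and roots reached 20 reads.

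In the Illumina stage comparison, 24 families were called. Per read matching a listed family 14 were called, and direction changed for miR168 (0.937), miR166 (0.678), miR167 (0.859), miR1425 (0.587) and miR1870 (0.742). Per 20 to 22 nt read 15 were called, and it changed for miR168 (0.999), miR166 (0.723), miR167 (0.916), miR1425 (0.626) and miR1870 (0.791). With TMM scaling 16 were called, and it changed for miR168 (0.843), miR166 (0.610), miR172 (0.905), miR167 (0.773), miR1425 (0.528) and miR1870 (0.668). Per read of the same length 21 were called, and it changed for miR168 (0.877), miR166 (0.634), miR172 (0.941), miR167 (0.804) and miR1425 (0.549). At 100 reads 14 were called, with 13 up and 1 down. The count was 25 per listed read and 27 with core matching, with 5 reads and with a ratio of 1.5.

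Tests of stage over the 4 grain libraries with a platform term called 0 families for both platforms with edgeR (1 at an unadjusted p under 0.05), with DESeq2 (4) and with DESeq2 on library totals (1). With edgeR, direction against Illumina changed for miR397 (0.974), miR168 (0.763), miR156 (0.879), miR166 (0.743), miR172 (0.861), miR535 (0.871), miR167 (0.202), miR164 (0.977), miR827 (0.822), miR169 (0.671), miR1425 (0.298), miR444 (0.511) and miR1870 (0.670), and against 454 for miR168 (0.763) and miR169 (0.671). With DESeq2 it changed for miR167 (0.467), miR1425 (0.468) and miR444 (0.930), and on library totals for miR397 (0.682), miR167 (0.474) and miR1425 (0.429).

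In the 454 stage comparison 2 families were called, 3 per read matching a listed family, 4 with core matching and 1 at 100 reads, and the direction of miR169 changed per 20 to 22 nt read (0.949), with TMM (0.959) and per read of the same length (0.773). Between shoots and roots 2 were called, and 0 per read matching a listed family, with TMM, per listed read and per read of the same length, with miR168 at 0.988 under TMM. Between grains and seedlings 1 family was lower in all pairs, 0 per read matching a listed family and with TMM, 2 with core matching, and 0 with edgeR on library totals (1 at an unadjusted p under 0.05) and with edgeR and TMM (0). miR171 changed direction at 1-5 DAF over shoots (3.65 per read matching a listed family, 2.38 with TMM), at 6-10 DAF over roots (1.12 and 1.21) and over shoots (1.06 and 1.18), and with core matching at 1-5 DAF over roots (0.947).

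Of all tags 12120 were called in Illumina, 2009 at 100 reads and 7364 per read of the same length, and between shoots and roots 22 were called and 3 at 100 reads. Between the 454 grain stages 67 were called and 7 at 100 reads. Without adapter tags 12097 were called in Illumina. Spearman's rho of the platforms was 0.207 at 100 reads and 0.451 with core matching at 1-5 DAF, and 0.591 and 0.185 at 6-10 DAF, and stage ratios had the same sign for 5 families with core matching. Without tags seen once the 24-nt share was 39.8% and 42.9% in 454 grains, 12.7% in roots, 15.2% in shoots, and 70.7% and 47.9% in Illumina grains. Without listed sequences it was 42.9% in roots, 53.8% in shoots, and 69.0% and 53.6% in Illumina grains. The opposite-arm share of Illumina grains of 6-10 DAF was 0.515% with core matching.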

Other observations

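The tests of spacing between 21-nt tags and of pairs of family members were chosen after the result was seen, and so were the members and tags named here, after their values were seen.

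Within 3 of 9 miRNA families, members differed in their ratio between the Illumina grain stages (4 of 13 pairs of members by Fisher's exact test on the reads of 2 members, with an adjusted p of 0.05 or less and ratios at least 2-fold apart). In the miR164 family, which targets NAC transcription factors, miR164e rose from 62 to 1306 reads (21.2-fold, 16.4 to 27.8) by Fisher's exact test. miR164a had a ratio of 1.08 (0.985 to 1.18) and miR164d of 0.935 (0.533 to 1.64). The fall of miR529 was in miR529a, from 467 to 127 reads (3.66-fold lower, 3.00 to 4.49), while miR529b had 12 reads at each stage (1.00, 0.413 to 2.44, exact adjusted p = 0.00509 for the pair). In the miR172 family, miR172a had a ratio of 2.90 (1.67 to 5.27) and miR172b of 1.04 (0.580 to 1.89, exact adjusted p = 0.0196 for the pair). Differences between members do not depend on the library denominator. The opposite arm of miR408 rose with its family, from 20 to 611 reads (30.7-fold, 19.7 to 50.6), and that of miR167 from 97 to 385 reads (3.99-fold, 3.18 to 5.04).

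Of the 8 most abundant 21-nt tags outside the lists that rose in Illumina, 7 were far higher at 6-10 DAF. ATATAGGAGTCACTCAGGAAA rose 47.2-fold to 12685 reads, TGCCCCACCAAGAGAACGCCG 39.7-fold to 10207 reads, TGGTGATGTTCTTCCGGCGGG 30.7-fold to 8055 reads and ATGCAAGTGATGTAGCGCCCC 22.3-fold to 10460 reads. TGATGCAAGTGATGTAGCGCC, TGCCTGAGGAACACCACCAGG and ATGAAGATGAATTGGAACATG rose 37.2-fold, 18.4-fold and 16.1-fold. TGGGAGTTCATGAAGCGGTCA rose only 2.11-fold, and was not called per 20 to 22 nt read (1.24) or per read of the same length (1.09). In 454, TGCCTGAGGAACACCACCAGG had 4 reads at 1-5 DAF and 25 at 6-10 DAF, ATGCAAGTGATGTAGCGCCCC had 2 and 15, and ATATAGGAGTCACTCAGGAAA had 2 and 8. Of the others, TGCCCCACCAAGAGAACGCCG, TGGTGATGTTCTTCCGGCGGG and TGGGAGTTCATGAAGCGGTCA had 0 and 1 reads there, and TGATGCAAGTGATGTAGCGCC and ATGAAGATGAATTGGAACATG had 0 and 0. In roots and shoots each of the 8 tags had 0 reads, which at a floor of 3 reads allows up to 138 and 253 RPM. Tags with overlapping sequences were counted separately. The tags that rose 22.3-fold and 37.2-fold share most of their bases, with shifted starts, so the 8 tags may not be 8 separate RNAs.

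Pieces of longer RNAs cut every 21 nt were looked for as a possible source of the called 21-nt tags, by joining overlapping tags. Of 159 pairs of called tags that start 12 to 30 nt apart, 13 lay 21 nt apart and 20 lay 12 nt apart, so the criterion written for the test, most pairs at 21 nt, was not met. Fewer joined stretches reach the longer distances (90 at 21 nt and 210 at 12 nt). Per stretch, a measure looked at only after these counts were seen, 21 nt had the highest share, 14.4%, followed by 17 nt with 11.8%. The share of the pairs at 21 nt was 0.0818 (0.0443 to 0.136), an interval that spans the bound of 0.1 set for random fragments of abundant RNAs, so neither source could be excluded. Some pairs share a tag or overlapping sequence, so the pairs are not independent and the interval is likely too narrow. Without a genome the tags cannot be placed on their precursors.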
